A study of Abies koreana with 6 samples.

How the data were processed

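Leaf RNA was sequenced from 3-year-old Korean fir (Abies koreana) seedlings from which water was withheld. Per the labels' protocols, 3 libraries came from seedlings sprayed with a culture of the yeast-like fungus Aureobasidium pullulans AK10 and 3 from seedlings sprayed with its growth medium, YPD broth, both with 250 µg/mL Tween-20. The culture had an optical density of 0.8, and seedlings were sprayed 3 times: a week (7 d) and then 4 d ahead of the drought, and again 4 d into it. Leaf surfaces were sterilised before extraction, 1 µg of total RNA went into a TruSeq library, and 101-bp paired-end reads were made on an Illumina HiSeq instrument, per the labels' protocols. No watered seedlings were analysed here.

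Per the file headers, the authors deposited read counts per gene model of the Douglas-fir annotation (Psme v1.0), so reads of one conifer species were counted on the genome of another. The submitters' processing notes name BWA, SAMtools, Subread and featureCounts, without roles or versions. Mapping options, the strand setting and the treatment of reads with several matches are not given in the sources used here. All 6 files listed the same 51419 models on 27126 scaffolds. The deposited RPKM values equalled the counts divided by model span and by the library's summed counts, to within a relative difference of 1e-5. The span ran from the first to the last base of the model, so it exceeded the coding length in 81.1% of models, with introns included. Where the species differ in sequence, or where a gene has close copies, reads can be lost or shared in such counts. Totals ran from 33004400 to 45414898 counted reads per library. Intervals and floors given for counts cover counting error only.

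Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit, trimmed mean of M values scaling, TMM, and filterByExpr with its minimum count of 10), which left 24355 models, with Benjamini-Hochberg adjustment and a threshold of 0.05. Normalised counts (CPM) are relative to the scaled library sizes, and fold changes set AK10 spray against broth spray. Standard errors were taken as the fold change on the log2 scale divided by the square root of the F value. The test was checked on simulated counts for the 24355 models with 200 of them changed: it recovered 9 of 100 models changed 2-fold and 76 of 100 changed 8-fold, and called 8 unchanged models. The labels do not say that the 3 libraries of a group came from separate seedlings, so p-values measure only the spread between these libraries. Libraries of a group differed by more than sampling noise (chi-square per model from 23.9 to 35.3), and each was counted as 1 sample, which leaves open whether they share plant material. The groups, tests, alternatives and the rule for named models were fixed before the data were examined. That rule names, where files do not pair models with gene names, the 2 models with the largest increase and the 2 with the largest decrease among those past the threshold whose libraries do not overlap between groups.

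The files do not pair models with gene names. The fixed design stated that in this case no gene list would be tested, and none of the 19 lists was. The families described here depart from that design. They are sets of models whose deposited protein sequence carries a short signature of a protein family. They were written once the files had shown protein sequences and before any test, 57 families in all, of which 17 of the 19 lists have at least 1 and 10 lie outside the lists. Those for organelle-type and psbA-type proteins were written after the most abundant models had been seen. A signature marks a likely family member, not a gene's identity, and misses members that lack it. The 51 families with at least 5 tested models were tested with camera (limma 3.58.1, voom values, preset correlation of 0.01), with camera and an estimated correlation, and with fry. On simulated counts camera called a set of 40 models lowered 2-fold and 0 of 50 random sets. These counts were drawn independently for each model. The check therefore could not show how the preset correlation behaves where members vary together, as chitinases did (estimated correlation 0.456). A first fit of these data had been looked at before the alternatives by total-count scaling, limma-voom, log2(RPKM + 1) and TMM without organelle-type models were added, and before most tests of the closing section were written.

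Near-identical models were looked for with BLAST 2.17.0 (at least 95% identity over at least 80% of the shorter protein). Library measures were compared with two-sided exact permutation tests, whose smallest p with 3 libraries against 3 is 0.1. Alternatives were no filter, a filter of RPKM 5 in 3 libraries, DESeq2 1.42.0 size factors and test, quantile normalization, limma on log2(RPKM + 0.1), robust empirical Bayes, a block for the replicate number, and each library left out in turn.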

Results

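Leaf transcripts of drought-stressed Korean fir seedlings were compared between AK10 spray (n = 3 libraries) and broth spray (n = 3 libraries). The comparison asks how leaf transcripts under drought differ between spray with the fungal culture and spray with its broth. No unsprayed seedlings were analysed here, so a decrease after AK10 spray was not told apart from an increase after broth spray. The broth-sprayed libraries held 33004400, 39409954 and 35740533 counted reads, and the AK10-sprayed libraries 43035662, 38405108 and 45414898.

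Much of each library came from few gene models. The 22 models with signatures of organelle-encoded proteins took 56.2% ± 2.97 (SD, n = 3) of reads after broth spray and 65.9% ± 1.51 after AK10 spray. Of these, the 6 models of the psbA type, which encodes the D1 protein of photosystem II, took 48.5% ± 3.78 and 57.5% ± 1.31. Models with at least 1 read numbered 35736 ± 126 after broth spray and 33068 ± 195 after AK10 spray. For each of these measures the libraries of the groups did not overlap, and the exact permutation p was 0.1, the smallest that 3 against 3 allows (adjusted 0.125 over 10 measures). Counted reads outside the organelle-type models were 15799225 ± 1727026 and 14387338 ± 690094 (exact permutation p = 0.3).

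**Figure D1:**
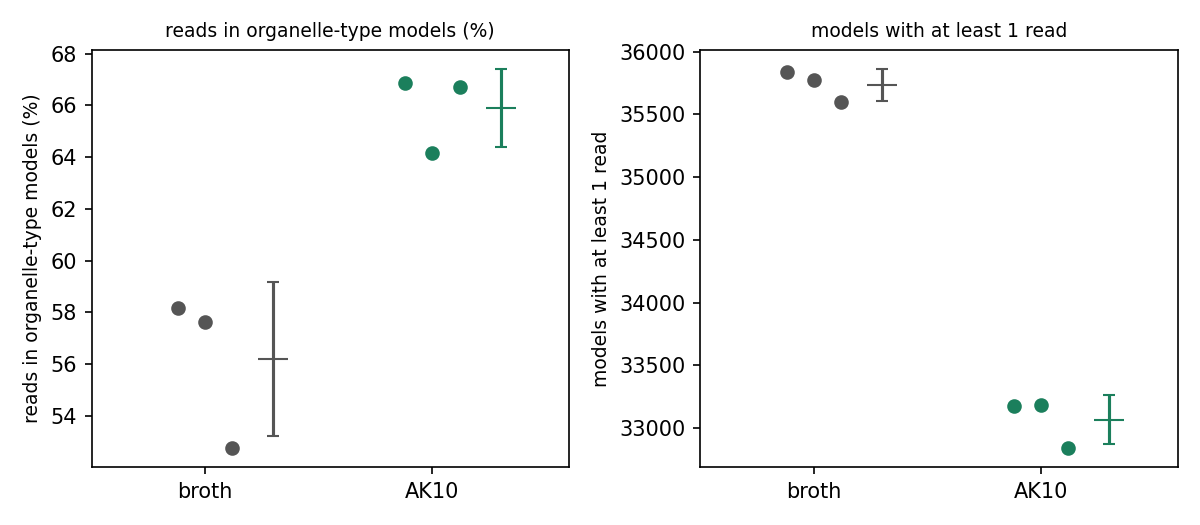
Percent of counted reads in organelle-type models (left) and number of models with at least 1 read (right) for each library (points), with mean and SD (bars, n = 3), and axes that do not start at 0. Every AK10-sprayed library lies above the broth-sprayed libraries on the left and below them on the right.

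On log2(CPM + 1) values the mean Pearson correlation was 0.973 within groups (from 0.966 to 0.977) and 0.956 between groups (from 0.938 to 0.969), so the ranges overlapped. These correlations are across genes, which are not independent replicates. The first principal component held 46.6% of the variance and parted the groups, with AK10-sprayed libraries from 18.2 to 42.6 and broth-sprayed libraries from -50.2 to -22.5.

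Of 24355 models tested, 40 were higher and 99 lower after AK10 spray at an adjusted p under 0.05 (edgeR quasi-likelihood test). Of these, 21 higher and 98 lower models differed by at least 2-fold. The size of change was larger among lower models, with a median of 3.49 on the log2 scale against 1.03 among higher models. At an unadjusted p under 0.05 there were 4703 models. The count of calls varied when single libraries were left out. It was 0, 48 and 74 without the third, second and first broth-sprayed libraries. It was 2, 10 and 378 without the third, first and second AK10-sprayed libraries. Each such fit also has fewer libraries, so lost power and the weight of 1 library were not told apart. The direction split depended on the scaling: with total counts, as in the deposited RPKM, the median of all models moved from -0.01 to -0.57 on the log2 scale and the split became 34 higher and 6230 lower.

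The largest increases were in PSME_43873 and PSME_51177. PSME_51177 carries a pectinesterase signature, an enzyme that removes methyl groups from cell wall pectin, and lies on scaffold jcf7190000015707 from 640875 to 643583. Its normalised count was 1.36 ± 0.290 CPM after broth spray and 9.92 ± 0.920 CPM after AK10 spray, a log2 fold change of 2.86 ± 0.23 (SE; edgeR adjusted p = 0.0107). PSME_43873 carries a GDSL lipase signature and lies on scaffold jcf7190000052874 from 87570 to 92698. It had 6 reads in all after broth spray and 106 after AK10 spray, a ratio of 22.2 with a 95% counting interval (Clopper-Pearson) from 9.88 to 61.9 (edgeR adjusted p = 0.0247). Both signatures were added after the called models had been seen.

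The largest decreases were in PSME_15793 and PSME_18616. PSME_15793 carries the signature of a class III peroxidase, a secreted enzyme acting on the cell wall, and lies on scaffold jcf7190000003400 from 54573 to 56287. It had 60, 47 and 46 reads after broth spray and 0 in each AK10-sprayed library, so it was at least 13.7-fold lower against a floor of 3 counts per library (edgeR adjusted p = 0.0289). PSME_18616, on scaffold jcf7190000019815 from 399265 to 400651, matched none of the signatures. Its reads were 203, 1384 and 626 after broth spray and 2, 1 and 2 after AK10 spray, a ratio of 352 with a 95% counting interval from 150 to 1084 (Clopper-Pearson), which leaves out the spread between libraries (edgeR adjusted p = 0.0247). No near-identical model was found for any of the 4 (0 each).

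Models detected in all libraries of one group at a mean of at least RPKM 1, and in none of the other, numbered 5 for broth spray and 0 for AK10 spray, against 0 to 2 in the other splits. None of the 5 carried a signature, and each had most of its reads in 1 broth-sprayed library, which was the first for 1 model (222 reads against 4 and 2) and the second for the other 4. With no minimum, 446 models were seen after broth spray alone and 46 after AK10 spray alone, against 74 to 181 in the other splits.

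Protein families were compared as sets of models sharing a signature, although the fixed design had foreseen no such test. With a preset correlation, camera called 14 of 51 families lower and 4 higher after AK10 spray. The split was 12 lower and 8 higher with total-count scaling, where class III peroxidases, phenylalanine ammonia-lyases and NB-ARC proteins lost the call (adjusted p = 0.149, 0.145 and 0.743), and 7 lower and 8 higher with limma on log2(RPKM + 1). NB-ARC proteins lost it also with no filter on low counts and with quantile normalization (adjusted p = 0.0957 and 0.0782). With an estimated correlation it called 0, with adjusted p of 0.22 or above for each, and 2 lower with no filter (multicopper oxidases and xyloglucan endotransglucosylases, adjusted p = 0.0382). The fry test called 2 lower and 1 higher, against 26 lower and 1 higher with total-count scaling, 29 and 1 with limma on log2(RPKM + 1), and 0 when broth-sprayed library 2 or 3 or AK10-sprayed library 1 or 3 was left out. Fry sets a family against no change, while camera sets it against the other models. With total counts the median of all models was -0.569, so fry calls there need not be particular to a family. DnaJ proteins passed there (fry adjusted p = 0.0105), although their median lay 0.004 from that of all models. Another split of the 6 libraries, mixing the groups, gave 24 families with the preset correlation, more than the 18 of the real split. The family differences are therefore given as values.

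Among families of the defence list, chitinases, which cut the chitin of fungal walls, had a median log2 fold change of -2.55 over 62 models (camera adjusted p = 1.24e-20; adjusted p = 0.338 with an estimated correlation). Of these, 2 were lower over all models tested and 48 were lower when adjusted over the list alone. Their summed count was 927 ± 427 CPM after broth spray and 215 ± 198 CPM after AK10 spray (SD, n = 3), and the libraries did not overlap. The second AK10-sprayed library carried much of the latter mean, which was 103 CPM without it. Thaumatin-like proteins had a median of -2.38 over 34 models (adjusted p = 0.338 with an estimated correlation), 3 lower over all models and 17 lower when adjusted over the list alone. Beta-1,3-glucanases, which cut glucans of fungal and plant walls, had a median of -1.95 over 31 models (adjusted p = 0.283 with an estimated correlation), 1 lower over all models and 21 lower when adjusted over the list alone. The second broth-sprayed library raised the thaumatin-like broth mean, which was 208 CPM with it and 123 CPM without it. NB-ARC resistance proteins had a median of -0.22 over 135 models (adjusted p = 0.220 with an estimated correlation), 0 past the threshold over all models and 1 lower when adjusted over the list alone.

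**Figure D2:**
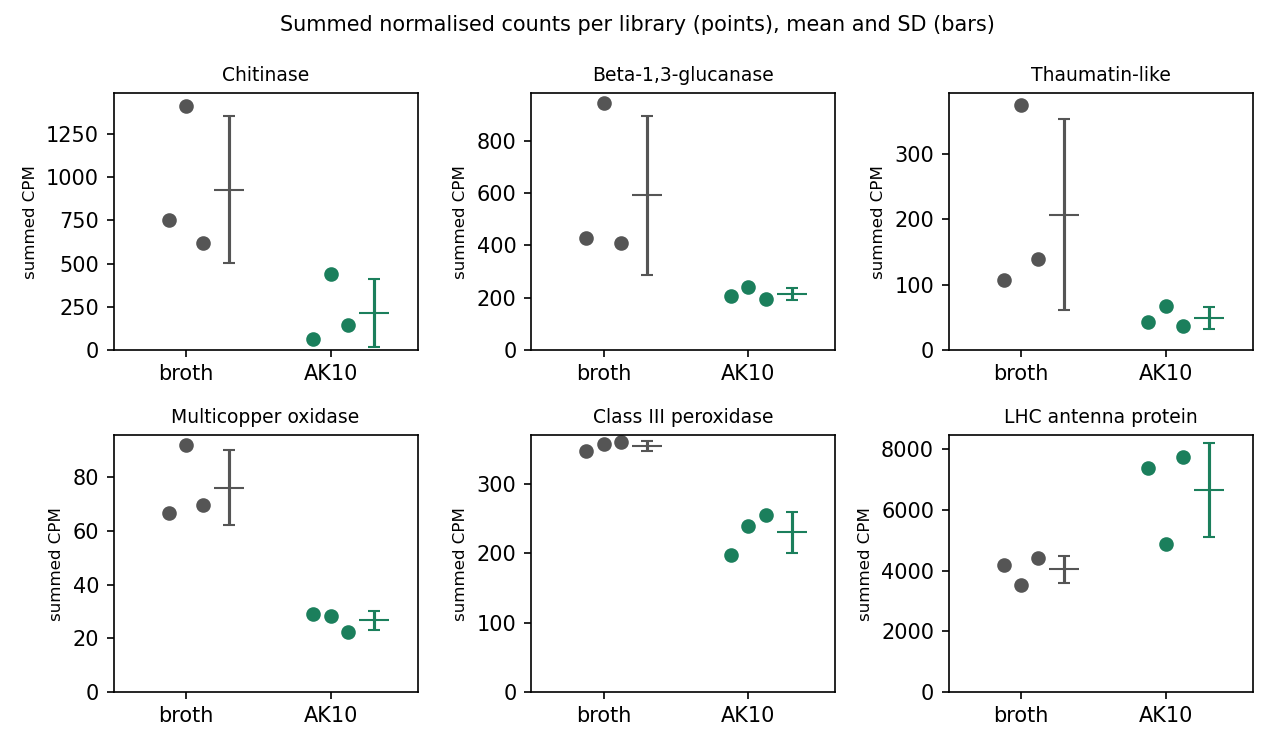
Summed normalised counts (CPM, axes from 0) of 6 families in each library (points), with mean and SD (bars, n = 3). The second broth-sprayed library holds the highest chitinase, glucanase and thaumatin-like sums, and antenna proteins run from 4036 CPM on average after broth spray to 6658 CPM after AK10 spray.

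Multicopper oxidases, which include laccases, had a median of -2.54 over 40 models, 2 lower over all models and 18 lower when adjusted over the list alone (adjusted p = 0.220 with an estimated correlation and 0.0440 with fry). Their summed count was 76.1 ± 13.96 CPM after broth spray and 26.6 ± 3.67 CPM after AK10 spray. Class III peroxidases, of the list for scavenging reactive oxygen, had a median of -1.07 over 75 models, 4 lower over all models, and 23 lower and 2 higher when adjusted over the list alone (adjusted p = 0.220 with an estimated correlation and 0.0440 with fry). Xyloglucan endotransglucosylases had a median of -0.82 over 41 models, with 3 lower over all models and 13 lower when adjusted over the list alone (adjusted p = 0.220 with an estimated correlation). Their summed count was 156.6 ± 29.2 CPM after broth spray and 124.5 ± 16.0 CPM after AK10 spray, and the groups overlapped. Phenylalanine ammonia-lyase, the entry enzyme of phenylpropanoid synthesis, had a median of -1.53 over 7 models, with 1 lower over all models (adjusted p = 0.338 with an estimated correlation). Its summed count was 69.8 ± 14.85 CPM after broth spray and 46.7 ± 30.6 CPM after AK10 spray, and the groups overlapped, since the first AK10-sprayed library held 82.0 CPM, above each broth-sprayed library, and the mean of that group was 29.0 CPM without it. The 3-ketoacyl-CoA synthases of wax synthesis had a median of -1.61 over 5 models, with 1 lower over all models (adjusted p = 0.338 with an estimated correlation). Neither 4-coumarate-CoA ligases, with a median of 0.07 over 5 models, nor zinc alcohol dehydrogenases, with 0.13 over 47, were called (camera adjusted p = 0.428 for both).

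Among signalling families, TIFY/JAZ proteins, repressors of jasmonate responses, had a median of -1.27 over 25 models, with 3 lower over all models, and 14 lower and 1 higher when adjusted over the list alone (adjusted p = 0.338 with an estimated correlation). AP2/ERF factors had a median of -0.52 over 56 models and WRKY factors of -0.51 over 48, with 0 past the threshold over all models in either (adjusted p = 0.338 for both with an estimated correlation). Summed counts differed less than these medians. The log2 ratio of sums was -0.36 for TIFY/JAZ, -0.04 for AP2/ERF and -0.24 for WRKY. Libraries of the groups overlapped in the sums of AP2/ERF (429 ± 15.8 and 419 ± 14.1 CPM) and WRKY (269 ± 23.3 and 228 ± 23.1 CPM), after broth and AK10 spray. EF-hand proteins and kinesins, both called with the preset correlation, had medians of -0.29 and -0.29 with 0 models past the threshold (adjusted p = 0.338 and 0.367 with an estimated correlation). Summed kinesin counts were 3090 ± 860 and 3167 ± 1018 CPM after broth and AK10 spray.

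Light-harvesting antenna proteins had a median of 0.60 over 11 models, all above 0, with 0 past the threshold over all models and 8 higher when adjusted over the list alone (adjusted p = 0.376 with an estimated correlation). Organelle-type models had a median of 0.76 over 22 models, with 0 higher over all models and 16 when adjusted over the list alone (adjusted p = 0.283 with an estimated correlation and 0.0440 with fry). The psbA type had a median of 0.79 over 6 models (adjusted p = 0.338 with an estimated correlation). Chalcone and stilbene synthases had a median of 0.64 over 12 models, 0 of which passed on either adjustment (adjusted p = 0.770 with an estimated correlation). Their summed count was 766 ± 195 CPM after broth spray and 1185 ± 695 CPM after AK10 spray, and the groups overlapped. The first AK10-sprayed library held 1956 CPM. Without it the log2 ratio of sums was 0.06, against 0.63 with it. Relative to the median of all models, the antenna median was 0.62 with TMM and 0.59 with total counts, and the organelle-type median 0.78 and 0.77. With quantile normalization, which sets the most abundant models of every library to equal values, they were 0.06 and -0.05 and 0 families were called higher.

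**Figure D3:**
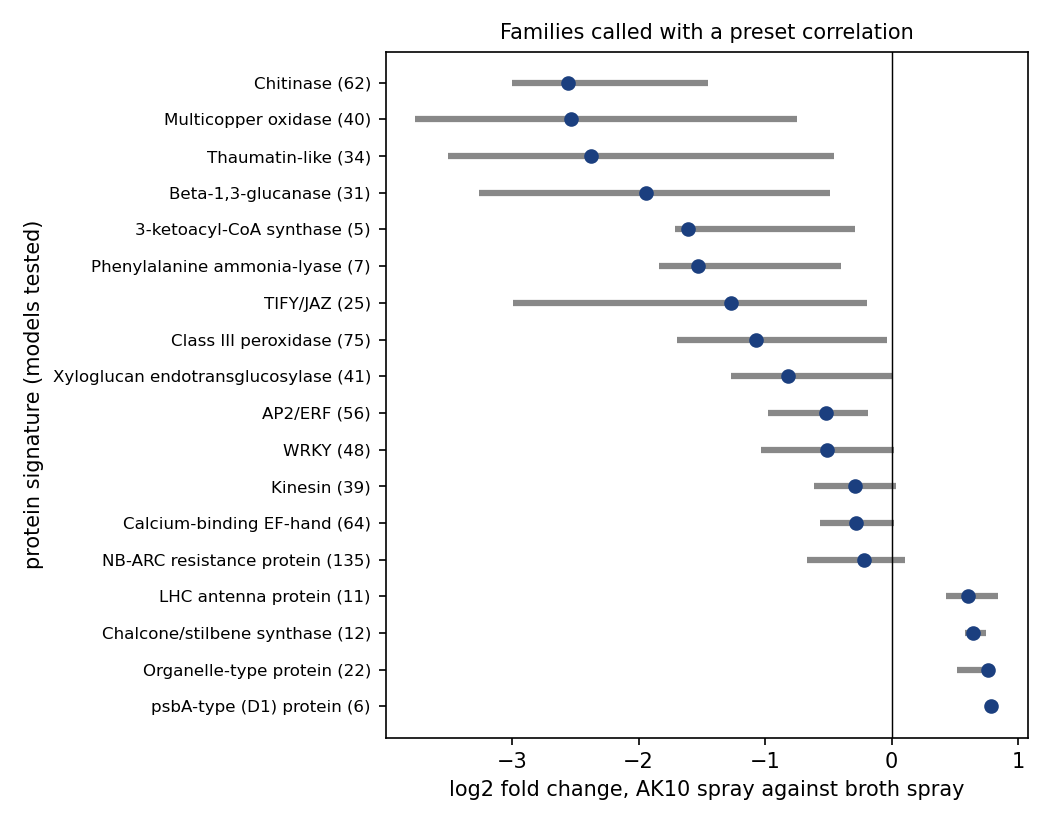
Median log2 fold change (points) and interquartile range (bars) over the models of each family that camera called with a preset correlation of 0.01; none was called with an estimated correlation. The medians run from -2.55 for chitinases to 0.79 for the psbA type.

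Dehydrins, abscisic acid receptors, aquaporins and galactinol synthases were not called with the filter on low counts. Dehydrins had a median of -0.65 over 14 models, the receptors, of the PYL type, of -0.98 over 14, aquaporins of -0.14 over 44 and galactinol synthases of 0.05 over 6. Camera's adjusted p with the preset correlation was 0.356, 0.0942, 0.477 and 0.638. With no filter the receptors were called lower, with a median of -1.25 over 35 models (camera adjusted p = 0.0138, and 0.523 with an estimated correlation). Germin-like proteins, catalases and cellulose synthases were then also called lower (camera adjusted p = 0.00531, 0.0343 and 0.0453, and 0.258, 0.641 and 0.593 with an estimated correlation). Although libraries of the groups overlapped, mean summed counts of dehydrins, the receptors and aquaporins lay the other way from their medians with the filter. After broth and AK10 spray they were 310 ± 64.6 and 330 ± 55.3 CPM for dehydrins, 36.4 ± 5.47 and 44.5 ± 3.01 CPM for the receptors, and 416 ± 56.0 and 455 ± 21.8 CPM for aquaporins (SD, n = 3). In all, 33 of the 51 families were not called, with medians from -1.36 for PR-1 proteins over 5 models to 0.70 for early light-inducible proteins over 9.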

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

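The scalings and tests by total counts, limma-voom, log2(RPKM + 1) and TMM without organelle-type models, the one-group count with no minimum, and all family tests were chosen after seeing the data. Against the 139 models called, 176 were called with DESeq2 size factors, 148 with quantile normalization, 182 with robust empirical Bayes and 140 with TMM without organelle-type models. Other settings moved the count by more than 1.5 times, with the count of changes of at least 2-fold (119) after it: 4301 and 531 with limma on log2(RPKM + 1), 4361 and 1537 on log2(RPKM + 0.1), 1339 and 935 with no filter, 0 and 0 with RPKM of at least 5 (647 of 2482 models at an unadjusted p under 0.05), 1800 and 1010 with the DESeq2 test, 6264 and 2863 with total-count scaling, and 8 and 8 with limma-voom. Leaving out single libraries gave from 0 to 378 calls, and from 0 to 310 of at least 2-fold. The cause was not tested. All 139 called models kept their sign in the settings that held them. The libraries of the groups did not overlap in any of these models, and the counts were the same, so a change of sign was hardly possible. With a replicate block, 295 models and 273 of at least 2-fold were called. Deviations of same-numbered libraries correlated at 0.007, 0.036 and -0.027, so the numbers were not taken as pairs. Families called numbered 18, against 7 with RPKM of at least 5, 0 with an estimated correlation (2 with no filter, 0 with a replicate block) and 3 with fry. The fry test takes in a shift of all models. It called 26 lower and 1 higher with total-count scaling and on log2(RPKM + 0.1), and 29 and 1 on log2(RPKM + 1). Without single libraries it called from 0 to 6. With a replicate block fry called AP2/ERF (0.0481) and TIFY/JAZ (0.0113), while multicopper oxidases, class III peroxidases and organelle-type models lost the call (0.155, 0.158 and 0.155, adjusted p). Models seen in one group numbered 5, against 492 with no minimum, 163 at RPKM 0.1, 2 at RPKM 5, and 5 to 22 without single libraries. The gap between mean correlations within and between groups was 0.0169, against 0.0238 with 0.1 added and 0.0230 by rank. Shares of the 10 and 100 most abundant models moved by less than 1 SD under the filter. Each named model kept its direction, which its selection on groups that do not overlap made likely. Each lost its call in 2 to 6 of 17 settings. Depth leaves the change of PSME_15793 as a bound, at least 13.7-fold lower against 3 counts per library.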

Other observations

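Signature sets written after the called models had been seen, and so not independent evidence, held further low models. Mandelonitrile lyase-like oxidoreductases had a median log2 fold change of -3.94 over 26 models, with 9 lower over all models tested, and a summed count of 168 ± 119 CPM after broth spray and 14.4 ± 0.913 CPM after AK10 spray (SD, n = 3; adjusted p = 0.140 with an estimated correlation). Without the second broth-sprayed library the broth mean was 99.2 CPM. Alpha-expansins, which loosen cell walls, had a median of -3.49 over 8 models with 2 lower, and polygalacturonase-type enzymes of -5.13 over 6 models with 3 lower. The expansin signature fixed before the tests had 2 tested models, too few for a family test, and with no filter on low counts a median of -0.29 over 10 models (camera adjusted p = 0.976). Pectinesterases had a median of -0.74 over 29 models, while the one called model among them was higher. Dirigent proteins had a median of -0.77 over 11 models with 1 lower. GDSL lipases, a set written at the same stage, had a median of 0.03 over 61 models. Of these, 31 lay above 0 and 30 below, and 1 was called, higher. Models with a fungal-type chitin synthase signature (3 in the annotation) had 12, 14 and 11 reads after broth spray and 7, 0 and 12 after AK10 spray.

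All tests of the weighed patterns were chosen after the results were seen, except the 2 on models with reads. Chitinase, thaumatin-like and beta-1,3-glucanase models had medians of -2.55, -2.38 and -1.95, although 2 of 62, 3 of 34 and 1 of 31 passed over all models and no family was called with an estimated correlation (adjusted p = 0.338, 0.338 and 0.283). The tables argue against one scaling shift of all models, since the members' median minus the all-model median was -2.412 with TMM. With DESeq2 size factors and total counts it was -2.415 and -2.34. The subtraction removes any factor common to a library, so these 3 had to nearly match. Quantile normalization, which can differ, gave -2.065. The tables argue against 1 control library, since the median was -1.96 or lower without each broth-sprayed library. They also argue against reads moved among the tested chitinase models or among the tested thaumatin-like models. Near-identical copies were not searched for in these families, and reads moved to models outside the tested ones were not examined. The log2 ratio of the summed counts of either family was -1.33 or lower without each library in turn. For glucanases that ratio was -1.47, and -0.97 without the second broth-sprayed library, short of the bound of -1, so such reads stay open there, as do an effect of the spray and an unrecorded batch.

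Fewer models had reads after AK10 spray. Thinning every library to 13764105 reads outside the organelle-type models left a difference of -2528 models, against -2668 before, so lower depth there does not account for it. Of the 446 models seen after broth spray alone, 8.1% belonged to the 14 families called lower, against 2.9% of all models with reads. The higher share was likely, since the families were called lower in the same data. Most of the 446 carried none of these signatures. Signatures miss members and these sets are small, so they could hardly have held most of the 446. Whether loss in such families accounts for the difference was therefore not decided. Genomic DNA in the broth-sprayed libraries and other differences in library making were not tested and stay open.

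Organelle-type and antenna models had medians of 0.76 and 0.60 on TMM values, with 0 past the threshold over all models and neither family called with an estimated correlation (adjusted p = 0.283 and 0.376). More organelle RNA captured in the AK10-sprayed libraries would not move nuclear antenna transcripts against other nuclear ones. The antenna median lay 0.593 or more above the all-model median with TMM, DESeq2 size factors and total counts. The subtraction removes any factor common to a library, so these scalings had to nearly match. Quantile normalization, which can differ, gave 0.059, but it sets the most abundant models of every library to equal values. Whether capture alone accounts for the antenna difference was therefore not decided. The antenna family was not called with an estimated correlation, so whether it differs beyond the spread between libraries stays open. The organelle-type median exceeded the antenna median by 0.156, less than the spread among antenna models. For the organelle-type models, capture and a change in the leaf therefore cannot be told apart.

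With 10 splits of the 6 libraries, no share under 0.05 can be reached. The real split gave 139 models and the highest other 0, so the splits with as many numbered 1, the real one. For changes of at least 2-fold it gave 119 and the highest other 0, again 1 split, the real one. For families it gave 18 and the highest other 24, and 4 splits, the real one included, gave at least 18. The median over chitinase, thaumatin-like and beta-1,3-glucanase models was -2.43 in the real split. The furthest from 0 in a split mixing the groups was -1.399. These families were grouped after they had been seen to be lower in the real split. That choice favours the real split, so no conclusion is drawn from the 2 values.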
